A study of Mus musculus with 30 samples.

How the data were processed

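Total RNA of brain, kidney, stomach, liver and salivary tissue of wild-type and ERRγ-null newborn mice was hybridized to Affymetrix MOE430A arrays, with 3 arrays per genotype and tissue and 30 in all. Per the labels, the mice were of mixed SV129 and C57BL/6 background, their sex is unknown and RNA was extracted with Trizol. The deposited log2 values are MAS5 signals per the submitters' processing notes, and the MAS5 version, the scaling target and the chip settings are not given in the sources used here. The base of the logarithm was settled from the values, since only with base 2 did the 2% trimmed mean of the linear values come out nearly equal on all arrays, between 149.988 and 150.008. Values ran from -6.64 to 13.45. All 30 columns were matched to a sample.

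The file held 22690 probe sets, of which 64 array controls were set aside and 22626 used. Gene symbols came from the probe table supplied with the data, which gave 1 symbol for 20380 probe sets, several for 691 and none for 1555. Probe sets with several symbols were tested and are not named. The symbols stood for 12393 genes. The 3' minus 5' difference of the Gapdh and Actb control probe sets was computed per array as a measure of RNA integrity.

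Design, tests, gene lists and alternatives were chosen before the data were examined. The design provided for a pseudocount unless values were already log2, so values were used as given with no further normalization. In each tissue, probe sets were tested whose mean over the 6 arrays reached the 40th percentile of the tissue. Null and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), Benjamini-Hochberg adjustment over the tested probe sets of the tissue and a threshold of adjusted p under 0.05. Reported differences are null minus wild-type on the log2 scale. Over all 30 arrays, a limma fit of 10 groups gave the average effect over tissues and an F test of its difference between tissues, for probe sets that passed the filter in at least 1 tissue.

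Gene lists, 52 in number with 1405 genes of which 1398 matched, were tested with camera of limma at a preset correlation of 0.01 between genes. Each gene was represented by the probe set with the highest mean over the 30 arrays, and lists needed 5 tested members. Adjustment was over the lists of the tissue, and members were counted as passing over all probe sets and as adjusted over the list alone. A correlation estimated from the data and the test fry were run as alternatives. Genes within 20 Mb of Esrrg were compared with others by Fisher's exact test, with gene order from a table on assembly GRCm38.p6.

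Named genes followed a rule: in each tissue, up to 12 rises and 12 falls by size of change among probe sets with 1 symbol, adjusted p under 0.05 and no overlap between the groups, or, where fewer than 5 passed in a direction, the 5 with the smallest p. Up to 4 members per list, 8 rises and 8 falls on average and 8 differences between tissues were named, besides Esrrg. Genes outside the rule are said to be chosen after their values were seen. Genes that passed in the same direction in several tissues were collected after the tests were run.

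The alternatives were a floor or a larger pseudocount in place of values as given, no filter or a filter at the 60th percentile, quantile normalization, equal array medians, a fit over all 30 arrays, the replicate number as a block, Xist as a covariate, no mean-variance trend, array weights, other thresholds and leaving out each array or tissue. Covariates for the Gapdh gap, Alb and Ucp1, and fits without arrays of high Alb or low Ucp1, were added after the data were seen.

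The steps were tested on simulated data with 200 changed probe sets of 13576 and the spread of each tissue. Of 2-fold changes 69.2% were recovered in brain, 76.6% in kidney, 71.9% in stomach, 52.2% in liver and 40.9% in salivary tissue, and of 4-fold changes 97.7%, 94.4%, 91.7%, 91.3% and 86.5%. False calls numbered 7, 7, 2, 8 and 4, and no probe set was called where nothing had been changed. Camera called 1 list in the brain and 1 in the stomach simulation where nothing had been changed. Simulated probe sets were drawn independently of each other, so these numbers do not show how camera behaves where genes are correlated.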

Results

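Gene expression was measured on Affymetrix MOE430A arrays in brain, kidney, stomach, liver and salivary tissue of newborn mice without ERRγ and of wild-type mice. ERRγ, encoded by Esrrg, is an orphan nuclear receptor of the estrogen-related receptor family, whose members drive genes of mitochondrial energy metabolism. The design held 5 tissues and 2 genotypes with 3 arrays in each of the 10 groups, 30 arrays in all, and this number limits the precision. The title given to the series names potassium homeostasis of heart, stomach and kidney as its subject, and heart was not analysed here. Values were log2 MAS5 signals of 22626 probe sets, with array medians between 5.80 and 6.08. The labels do not say that the 3 arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. Wild-type arrays held the transcripts of their tissue: Atp4a of the gastric proton pump stood at 10.46 ± 0.11 in stomach (SD, n = 3). Serum albumin Alb stood at 12.94 ± 0.07 in liver, uromodulin Umod at 10.75 ± 0.29 in kidney, the synaptic gene Snap25 at 10.02 ± 0.21 in brain and the salivary protein gene Bpifa2 at 12.93 ± 0.06 in salivary tissue. Xist, expressed from the inactive X chromosome, was high in 2 of the 3 arrays of each group and low in the other in all 5 tissues, so both genotypes held the same mix of sexes by this measure and the arrays of a group were not all from 1 animal.

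Esrrg itself was represented by 1 dim probe set, whose position relative to the deleted part of the gene is not given in the sources used here, so it does not check the genotype labels. It read 6.01 ± 0.18 in wild-type and 6.17 ± 0.15 in null brain (SD, n = 3), 6.02 ± 0.05 and 6.09 ± 0.07 in kidney, 6.49 ± 0.16 and 6.47 ± 0.29 in liver, and 6.41 ± 0.14 and 6.39 ± 0.23 in salivary tissue. These differences did not pass the test. In stomach it was higher in null arrays, 6.48 ± 0.09 against 5.99 ± 0.05, a difference of 0.49 ± 0.13 (SE; limma, Benjamini-Hochberg adjusted p = 0.0312). There 23.5% of all tested probe sets passed, and the control 3' minus 5' difference was larger in null arrays. With that of Gapdh as a covariate, a setting chosen after the data were seen, the call of Esrrg was lost. A two-sided exact permutation test of the 3 against 3 arrays gave p = 0.1 in stomach, which is the smallest it can give.

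The comparison of null with wild-type stomach asked which gastric transcripts depend on ERRγ. Both subunits of the gastric proton pump, which acidifies gastric juice in exchange for potassium, fell. Atp4a, the catalytic subunit, fell by 5.04 ± 0.12 on the log2 scale (SE), from 10.46 ± 0.11 to 5.43 ± 0.13 (SD, n = 3; limma, adjusted p = 2.31e-07), and Atp4b, its partner, fell by 4.81 ± 0.14, from 11.19 ± 0.14 to 6.38 ± 0.23 (limma, adjusted p = 5.87e-07). Null values of Atp4a, 5.33 to 5.58, lay among those of the 24 arrays of the other tissues, 5.34 to 5.95, and null Atp4b, 6.15 to 6.60, lay near theirs, 3.62 to 6.51, so background bounds these folds. Slc4a2, the basolateral chloride-bicarbonate exchanger of parietal cells, fell by 1.45 ± 0.13 (limma, adjusted p = 0.000771), and Kcnq1, the potassium channel that returns potassium to the gastric lumen, fell by 1.26 ± 0.14 (limma, adjusted p = 0.00139). The carbonic anhydrase Car2 (-0.84) and Cblif (-0.76), which encodes intrinsic factor, also fell. Cblif is on the chief cell list as well, so its fall is not particular to parietal cells. Of the 10 measured members of the parietal cell list these 6 fell and 4 did not pass, with 6 lower adjusted over the list alone. The list was lower by camera (adjusted p = 2.52e-05, and adjusted p = 0.508 with an estimated correlation). Beside this list and those that follow, the control transcripts' 3' minus 5' gap, a measure of RNA integrity, was larger by 1.13 in null than in wild-type stomach. With the Gapdh gap as a covariate, an alternative chosen after the data were seen, camera called the parietal list at a mean of -1.23 against -1.46.

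**Figure D1:**
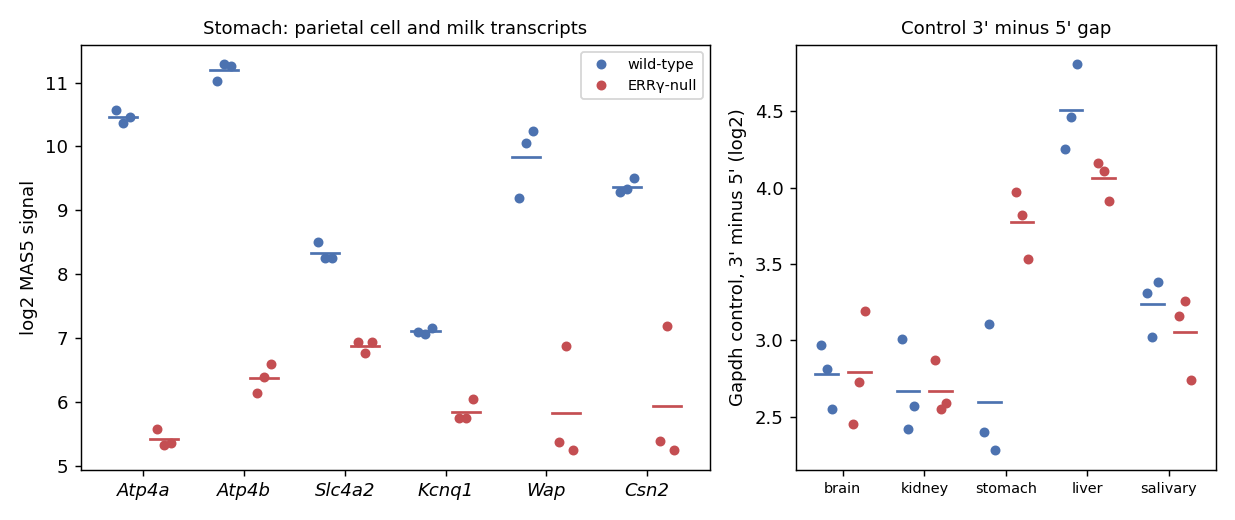
Left, log2 MAS5 signal of 6 transcripts in stomach, and right, the Gapdh control 3' minus 5' difference (log2) in 5 tissues, with 1 point per array and a line at the mean of each group of 3. Atp4a lay between 10.36 and 10.57 in wild-type and between 5.33 and 5.58 in null stomach, and the mean Gapdh gap was larger by 1.18 in null stomach.

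Potassium channels and pumps beyond these moved both ways in stomach. Of 28 measured members 6 fell, 2 rose and 20 did not pass, with 7 lower and 4 higher adjusted over the list alone. Besides Atp4a, Atp4b and Kcnq1 the falls were the potassium-chloride cotransporter Slc12a4 (-1.02), the channel gene Kcnh2 (-0.73) and the sodium pump subunit Atp1b3 (-0.57), while the cotransporter Slc12a2 (0.55) and the sodium pump subunit Atp1b1 (0.61) rose. The median of the list was 0.11, its mean was -0.31 and the limma test camera ranked it lower without passing (adjusted p = 0.673), so these measures differ in sign. The channel subunits Kcne2 and Kcne1 belong to the list, but their means over the 6 arrays lay under the filter, and they were singled out after their values were seen. Kcne2, which pairs with Kcnq1 in parietal cells, read 6.84 ± 0.26 in wild-type and 3.09 ± 1.85 in null stomach (SD, n = 3), and Kcne1 read 4.27 ± 0.60 and 0.85 ± 0.18. Tested without the filter, Kcne2 differed by -3.75 ± 0.80 (limma, adjusted p = 0.0263), a value that background bounds because its null mean lay under the level of the filter (5.35). Both means of Kcne1 lay under that level, so no difference is given for it. The proton transport list, which holds the gastric pump, had 7 lower, 2 higher and 12 not passing of 21 (8 lower and 3 higher adjusted over the list alone), with Car12 at -0.90, and was lower by camera (adjusted p = 0.0252, and adjusted p = 0.508 with an estimated correlation). It was not called without null replicate 2 (mean -0.65 against -0.64), without the filter (-0.40) or with Alb as a covariate (-0.58).

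Among milk transcripts, the caseins Csn1s2a (-6.00), Csn2 (-3.42), Csn3 (-3.04) and Csn1s1 (-2.61) fell in null stomach. Whey acidic protein Wap (-3.99) and Wfdc18 (-2.73), which read up to 12.49 in another tissue, fell too. Swallowed milk may bring such transcripts into a stomach sample, so these falls are not read as changes of gastric cells. Milk intake is weighed in the closing part. The milk transcripts differed among null arrays, with Csn2 at 5.40, 7.20 and 5.25 and Wap at 5.38, 6.88 and 5.26 in replicates 1, 2 and 3. The 1 other tested probe set of Csn1s2a also fell, by 4 or more from a wild-type mean of at least 10.46. A further, dim probe set of this gene lay under the filter at 4.35 ± 0.07 in wild-type and 4.60 ± 0.15 in null stomach (SD, n = 3). Alpha-fetoprotein Afp (-4.01), the mesothelial uroplakin Upk3b (-2.63), Pitpnb (-2.69) and the G protein subunit Gnb2 (-2.58) completed the 12 named falls. Afp did not pass without wild-type replicate 2 (-3.98) or null replicate 1 (-4.14), nor Upk3b without wild-type replicate 2 (-2.59) or 3 (-2.56) or null replicate 3 (-2.73). The named rises were the transcription factor Cebpd (2.51), Pdk4 (2.45), a kinase that restrains pyruvate dehydrogenase, and the ubiquitin ligases Fbxo32 (2.44) and Ube3a (2.28). Trp53inp1 (2.25), Maff (2.06), the epithelial factor Ehf (2.01) and the BMP receptor Bmpr2 (2.0) rose too. Txnrd1 (2.98), Hif1a (2.62), Birc6 (2.13) and Ubtf (1.98) also rose at the named probe set, but 1 of 1, 2 of 2, 1 of 2 and 1 of 1 of their other tested probe sets went the opposite way. Wild-type means of Txnrd1, Hif1a, Ube3a, Maff, Ehf and Ubtf and null means of Csn1s2a, Afp, Csn3, Pitpnb and Upk3b lay under the level of the filter, so background bounds these changes.

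Cell cycle genes fell in null stomach, with 32 of 36 measured members lower and 4 not passing (35 lower and 1 higher adjusted over the list alone). Thymidine kinase Tk1 (-2.14), the replication helicase subunits Mcm5 (-2.05) and Mcm3 (-1.51) and the checkpoint kinase Bub1b (-1.93) led them (camera, adjusted p = 3.58e-16, and adjusted p = 0.508 with an estimated correlation). Glucocorticoid-responsive genes rose, 11 of 13 with 2 not passing (11 higher adjusted over the list alone), among them Klf9 (1.94), Errfi1 (1.67), Tsc22d3 (1.46) and Fkbp5 (1.45) (camera, adjusted p = 2.52e-05, and adjusted p = 0.508 with an estimated correlation). Immediate early genes rose in 10 of 23 members, with Fos (1.44), Klf6 (1.39) and Dusp1 (1.24), and 10 were higher adjusted over the list alone. Circadian genes rose in 5 of 12, with Usp2 (1.0) and Per1 (0.70), and 6 adjusted over the list alone. Squamous epithelium genes rose in 9 of 16 with 2 lower, among them Sprr1a (1.19), Dsc3 (1.08) and Krt6a (0.84), with 10 higher and 2 lower adjusted over the list alone. Ribosomal protein genes rose in 12 of 41 with 1 lower, such as Rps24 (0.57) and Rps9 (0.57), with 15 higher and 1 lower adjusted over the list alone. Camera placed these 4 lists higher (adjusted p = 0.000306, 0.00328, 0.00819 and 0.000629 in that order), and each had adjusted p = 0.508 with an estimated correlation. The squamous list was not called without null replicate 2 (mean 0.34 against 0.40), and the ribosomal list was not called after quantile normalization (mean 0.03 against 0.18). With the Gapdh gap, which was larger in null stomach, as a covariate camera called neither the immediate early list (0.35 against 0.56) nor the ribosomal list (-0.00499), and it called the cell cycle (-1.03), glucocorticoid-responsive (1.08), circadian (0.63) and squamous (0.43) lists.

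Lists of mitochondrial energy metabolism were lower by camera in null stomach, where the Gapdh gap was larger. Of 76 oxidative phosphorylation genes 27 fell, 2 rose and 47 did not pass (31 lower and 2 higher adjusted over the list alone), with Ndufs5 (-1.04), Uqcrc1 (-1.03) and Ndufab1 (-0.92) as examples. Of 38 fatty acid oxidation genes 14 fell, 4 rose and 20 did not pass (17 lower and 4 higher adjusted over the list alone), with the fatty acid binding protein Fabp3 (-2.54), Etfb (-1.19) and Acaa1b (-1.20) lower and Pdk4 higher. Of 24 tricarboxylic acid cycle genes 8 fell, 1 rose and 15 did not pass (12 lower and 1 higher adjusted over the list alone), led by Idh2 (-0.98) and Ogdh (-0.98). Of 59 mitochondrial ribosome and translation genes 17 fell (19 adjusted over the list alone), led by Mrpl12 (-1.74). Camera gave adjusted p = 2.52e-05, 0.00547, 0.00328 and 2.74e-05 for these 4 lists, and each had adjusted p = 0.508 with an estimated correlation. With the Gapdh gap as a covariate camera called neither the fatty acid oxidation list (mean -0.21 against -0.27) nor the tricarboxylic acid cycle list (-0.09 against -0.30), and it called the oxidative phosphorylation (-0.33) and mitochondrial ribosome (-0.34) lists. Cholesterol synthesis genes fell in 6 of 18 members, as they did adjusted over the list alone, with Fdps (-1.81), Msmo1 (-1.26) and Cyp51 (-0.87) (camera, adjusted p = 0.00999, and adjusted p = 0.661 with an estimated correlation). Hepatocyte genes fell in 2 of 17, Afp and Ambp (-2.53), with 1 adjusted over the list alone (camera, adjusted p = 0.00999, and adjusted p = 0.726 with an estimated correlation), beside Alb values of 5.93, 10.25 and 11.90 in the wild-type and 6.81, 6.19 and 7.06 in the null arrays. The hepatocyte list was not called without wild-type replicate 3 (mean -0.62 against -1.48) or null replicate 2 (-1.29), nor with array weights (-1.28). It was not called with the Gapdh gap (-0.29) or Alb (0.00393) as a covariate or without the 2 wild-type arrays of high Alb (-0.14), and the cholesterol list was not called with Alb (-0.31 against -0.40) or without those arrays (-0.30).

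In stomach 3186 of 13576 tested probe sets passed (limma, adjusted p under 0.05), 1527 higher and 1659 lower, standing for 1184 and 1361 genes, with 16 higher and 32 lower by 4-fold or more. The 3 null and 3 wild-type values did not overlap for 42.8% of tested probe sets, against 10% by chance. The control transcripts differed with genotype in the same arrays: the 3' minus 5' difference, a measure of RNA integrity averaged over Gapdh and Actb, was 3.22 ± 0.34 in null and 2.09 ± 0.43 in wild-type stomach (SD, n = 3). With the array's Gapdh gap as a covariate 2 probe sets passed, Atp4a (-4.96) and Atp4b (-4.72). Without the 2 wild-type arrays with high Alb 28 passed, and with Alb as a covariate 504. Of the gene results named for stomach 57 of 69 lost the call in the first and 35 of 74 in the second. Leaving out wild-type replicate 2 or 3 or null replicate 1 or 3 gave 1888, 1461, 1665 and 1666.

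In kidney the comparison asked the same question for renal transcripts. Kcnj1, the ROMK potassium channel through which the thick ascending limb and collecting duct secrete potassium, fell by 1.08 ± 0.13 (SE), from 8.71 ± 0.23 to 7.63 ± 0.08 (SD, n = 3; limma, adjusted p = 0.0126). Carbonic anhydrase Car2 fell by 1.28 ± 0.10, from 9.99 ± 0.08 to 8.71 ± 0.07 (limma, adjusted p = 0.000645). Uromodulin Umod (-1.45), the most abundant urinary protein, Klotho Kl (-1.25), a co-receptor for the phosphate hormone FGF23, the angiotensin receptor-associated gene Agtrap (-1.86), the proximal tubule enzyme Miox (-1.71) and the dicarboxylate transporter Slc13a3 (-1.61) fell too. Tmsb10 (-1.70), Egfl6 (-1.68), Gpx6 (-1.26), Dhrs1 (-1.01) and Bola2 (-1.60, with 1 of 3 other probe sets opposite) completed the 12 named falls. The rises were led by Cebpd (2.43 ± 0.16; limma, adjusted p = 0.00055), Sprr2f (2.31), Igfbp1 (1.85 ± 0.14; limma, adjusted p = 0.000645), an insulin-like growth factor binding protein, and Cyp27b1 (1.69), the enzyme that activates vitamin D. Usp2 (1.63), Sult1a1 (1.59), Errfi1 (1.57), Arg2 (1.56), Klf9 (1.52), Herpud1 (1.48), S100a14 (1.31) and Ccn2 (1.30) followed. Null means of Agtrap, Tmsb10, Egfl6, Slc13a3 and Bola2 and the wild-type mean of S100a14 lay under the level of the filter, so background bounds these changes.

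Renal kallikrein Klk1 was singled out after its values were seen, and the means of its 3 probe sets over the 6 arrays lay under the filter. They read 7.04 ± 0.57, 6.91 ± 0.56 and 7.48 ± 0.42 in wild-type and 1.35 ± 0.82, 1.52 ± 1.47 and 2.39 ± 1.86 in null kidney (SD, n = 3), so low null values put them there. Tested without the filter, the differences were -5.68 (limma, adjusted p = 0.0084), -5.39 (limma, adjusted p = 0.0496) and -5.09 (limma, adjusted p = 0.0804, not passing). Null means lay under the level of the filter (5.39), so background bounds these differences. Klk1 belongs to the distal tubule and glandular duct lists through the last of these, and neither list's count holds it in kidney.

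By renal segment few genes passed. In the thick ascending limb list 2 of 11 members fell, Umod (-1.02 at the probe set the lists use, the brightest over all arrays) and the claudin Cldn10 (-0.86), with 3 lower and 1 higher adjusted over the list alone. Ptger3 (-1.04) and Irx1 (0.42) did not pass. Kcnj1 belongs to this list and to the potassium list, but its list probe set lay under the filter at 2.34 ± 0.66 in wild-type and 2.75 ± 1.51 in null kidney (SD, n = 3), so neither count holds it. Among 31 potassium channels and pumps 0 passed over all genes and 3 were higher adjusted over the list alone, with Kcnj8 at 0.85, Kcnk1 at 0.50 and Kcnj15 at 0.50, none past the limma threshold. Neither list was called by the limma test camera (adjusted p = 0.162 and 0.0578). Without null replicate 2 camera called the thick ascending limb list (mean -0.47 against -0.23), and without wild-type replicate 1 (mean 0.17) or null replicate 1 (0.17) the potassium list (0.13). The first was also called without the filter (-0.39) or with a larger pseudocount (-0.32), and the second with the stricter filter (0.16), array weights (0.14) or equal array medians (0.07). In the intercalated cell list Car2 was the 1 fall of 8, with 2 lower adjusted over the list alone and Car12 at -0.47 (limma camera, adjusted p = 0.119), and camera called it without null replicate 1 (mean -0.31 against -0.21) or without the filter (-0.50). The distal tubule list had 0 of 9 passing and 2 higher adjusted over the list alone, with Calb1 at 0.55 (limma camera, adjusted p = 0.0578), and camera called it without wild-type replicate 1 (mean 0.32 against 0.23) or null replicate 1 (0.25), with the stricter filter (0.24), array weights (0.24), quantile normalization (0.22), the replicate block (0.23) or equal array medians (0.17). Its mean was below 0, with no call, without null replicate 2 (-0.25) or 3 (-0.28), without the filter (-0.24) and with a larger pseudocount (-0.10). In the principal cell list 0 of 13 passed, 3 were higher and 2 lower adjusted over the list alone, with Aqp2 at 0.89 and Hsd11b2, which inactivates glucocorticoid, at -1.13 (camera higher, adjusted p = 0.0362, and adjusted p = 0.348 with an estimated correlation). It was not called without wild-type replicate 3 (mean 0.14 against 0.16) or null replicate 2 (0.18) or 3 (0.13), nor without the filter (0.14) or the mean-variance trend (0.16).

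Proximal tubule genes were lower as a list. Of 28 members 3 fell, Miox and Slc13a3 among them, 2 rose, Cyp2e1 (1.08) and Pck1 (1.01), and 23 did not pass, with 10 lower and 4 higher adjusted over the list alone (camera, adjusted p = 0.000918, and adjusted p = 0.377 with an estimated correlation). In the renin-angiotensin and mineralocorticoid list Sgk1 (1.02), a kinase induced by corticosteroids, was the 1 rise of 18, with 1 higher and 2 lower adjusted over the list alone (limma camera, adjusted p = 0.13). Glucocorticoid-responsive genes rose in 7 of 15 members, Errfi1, Klf9 (1.35 at the list's probe set), Sgk1 and Pck1 among them, with 11 higher adjusted over the list alone (camera, adjusted p = 4.89e-13, and adjusted p = 0.284 with an estimated correlation). Immediate early genes rose in 2 of 20, Ccn2 and Klf6 (1.04), with 11 adjusted over the list alone, and circadian genes in 1 of 11, Usp2 (1.21), with 4 adjusted over the list alone. Camera gave adjusted p = 7.98e-09 and 0.00166 for them, each with adjusted p = 0.284 with an estimated correlation. Oxidative phosphorylation genes fell in 1 of 76, Atp5g1 (-0.71), with 24 lower and 1 higher adjusted over the list alone, and 67 of the 76 estimates lay below 0. Fatty acid oxidation genes fell in 2 of 39, Acaa1b (-0.84) and the medium-chain dehydrogenase Acadm (-0.55), with 16 lower and 3 higher adjusted over the list alone. Tricarboxylic acid cycle genes had 0 of 24 passing, 6 lower adjusted over the list alone and 23 of 24 estimates below 0, with Pdhb at -0.39. Mitochondrial ribosome genes had 0 of 60 passing and 0 adjusted over the list alone, with Mrps25 at -0.71. Camera placed these 4 lists lower (adjusted p = 5.64e-14, 0.000168, 1.40e-06 and 8.36e-05), and they had adjusted p = 0.348, 0.348, 0.284 and 0.284 with an estimated correlation.

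Cell cycle genes fell in 3 of 37 members in kidney, Ube2c (-0.79), Cdk1 (-0.56) and Cks2 (-0.56), with 16 adjusted over the list alone (camera, adjusted p = 1.12e-13, and adjusted p = 0.284 with an estimated correlation). Xenobiotic metabolism genes rose in 2 of 15, Sult1a1 and Cyp2e1 (5 higher and 1 lower adjusted over the list alone), hypoxia-responsive genes in 1 of 15, Ndrg1 (0.97) (2 higher adjusted over the list alone), and hepatocyte genes in 1 of 13, the fibrinogen chain Fga (1.28) (3 higher and 1 lower adjusted over the list alone). Camera gave adjusted p = 0.0121, 0.016 and 0.0295 for these, and adjusted p = 0.348, 0.348 and 0.476 with an estimated correlation. The hypoxia list was not called without null replicate 1 (mean 0.22 against 0.31), nor the hepatocyte list without wild-type replicate 1 (0.28 against 0.36) or null replicate 2 (0.17), nor the xenobiotic list with the stricter filter (0.39 against 0.42). Heat shock genes fell in 1 of 16, Hsph1 (-0.66), and choroid plexus genes in 1 of 8, which was Kl, with 1 and 2 lower adjusted over the list alone (camera, adjusted p = 0.0304 and 0.03, and adjusted p = 0.377 and 0.348 with an estimated correlation). The heat shock list was not called without wild-type replicate 2 (mean -0.12 against -0.13) or null replicate 1 (-0.09) or 2 (-0.12), and the choroid plexus list not without null replicate 3 (-0.22 against -0.26), without the filter (-0.03), with the stricter filter (-0.25) or after quantile normalization (-0.25). Granulocyte and glandular duct genes had 0 of 9 and 0 of 17 passing and 0 adjusted over each list alone, with Ngp at 0.44 and Krt19 at 0.49. They were higher by camera (adjusted p = 0.0362 and 0.0108, and adjusted p = 0.444 and 0.348 with an estimated correlation). Without null replicate 2 neither was called (means 0.33 against 0.30 and -0.12 against 0.19). Neither was called without wild-type replicate 3 (0.30 and 0.15), and without null replicate 3 the mean of the duct list was -0.04 while camera still called it higher. The granulocyte list was not called without wild-type replicate 2 (0.18) or null replicate 1 (0.27) either. Without the filter neither was called (0.35 and -0.15), and neither was the granulocyte list after quantile normalization (0.24) nor the duct list with a larger pseudocount (0.005).

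In kidney 106 of 13577 tested probe sets passed (limma, adjusted p under 0.05), 56 higher and 50 lower, standing for 43 and 44 genes, with 3 higher and 0 lower by 4-fold or more. With array medians made equal the split was 54 higher and 106 lower. The count rested on single arrays: it was 7, 4 and 22 without wild-type replicates 1, 2 and 3, and 26, 295 and 29 without null replicates 1, 2 and 3. Of the 24 named genes Cebpd, Igfbp1 and Car2 passed without each array in turn. Only 2 of the 24, Cebpd and Car2, also kept the call in every other planned setting. In the fit over all 30 arrays Igfbp1, Kcnj1, Kl, Slc13a3, Umod and Miox were among those that did not pass. Kcnj1 did not pass without wild-type replicate 1 (-1.06) or 2 (-0.97), nor Kl (-1.21 and -1.19), Slc13a3 (-1.61 and -1.62) or Umod (-1.43 and -1.43). Miox did not pass without wild-type replicate 1 (-1.76) or 2 (-1.73) or null replicate 1 (-1.65). The Umod probe set that the lists use (-1.02) did not pass without wild-type replicate 1 (-0.87), 2 (-1.05) or 3 (-1.15) or null replicate 1 (-0.95).

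Genes of fasting and gluconeogenesis were higher in null liver as a list. Ppargc1a, the coactivator of ERR receptors and of gluconeogenic genes, rose by 2.74 ± 0.27 (SE), from 7.16 ± 0.32 to 9.90 ± 0.56 (SD, n = 3; limma, adjusted p = 0.00193). Tyrosine aminotransferase Tat rose by 2.58 ± 0.33 (limma, adjusted p = 0.00435) and the aspartate aminotransferase Got1 by 3.43 ± 0.36 (limma, adjusted p = 0.00224). Of the 20 measured members of the fasting and gluconeogenesis list 9 rose, Lpin1 (2.50) among them, 2 fell and 9 did not pass, with 11 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.00027, and adjusted p = 0.428 with an estimated correlation). Among ERR family members and partners 6 of 19 rose, as they did adjusted over the list alone, and 13 did not pass. They included Ppargc1a, its relative Ppargc1b (1.98), the receptor Esrra (1.01) and the deacetylase Sirt1 (0.86) (camera, adjusted p = 0.000306, and adjusted p = 0.428 with an estimated correlation). The other named rises were Plk3 (5.0), Gadd45b (4.66), the uridine phosphorylase Upp2 (3.98) and Ddit4 (3.26), an inhibitor of mTOR signalling. Rab30 (3.13), Pim3 (3.12), Retreg1 (2.86), a receptor for autophagy of the endoplasmic reticulum, the clock gene Cry2 (2.71) and Trp53inp1 (2.61) rose as well. Wild-type means of Plk3 (2.87), Gadd45b (3.91) and Cry2 (4.12) lay under the level of the filter (5.25), so background bounds these rises.

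The named falls in liver were led by the aldo-keto reductase Akr1c6 (-4.64 ± 0.39; limma, adjusted p = 0.00114), the cytochrome Cyp1a2 (-4.63) and carbonic anhydrase Car3 (-4.21). The activin subunit Inhba (-3.60), Akr1c20 (-3.28), the aldehyde oxidase Aox3 (-3.11), Cyp4a12a (-3.09), G0s2 (-3.02), an inhibitor of adipose triglyceride lipase, Akr1c14 (-3.00), Pcolce2 (-2.77), Ppp1r3c (-2.71), which targets phosphatase to glycogen, and Pbld2 (-2.66) followed. Null means of Cyp1a2, Inhba, Cyp4a12a and Pbld2 lay under the level of the filter, which bounds these falls in the same way. Cholesterol synthesis genes fell in 9 of 17 members with 1 higher, Msmo1 (-1.85), Hmgcs1 (-1.77), Sqle (-1.71) and Idi1 (-1.71) among them, and 10 lower and 1 higher adjusted over the list alone (camera, adjusted p = 2.17e-06, and adjusted p = 0.428 with an estimated correlation). Lipogenesis genes went both ways: 3 of 18 fell, fatty acid synthase Fasn (-1.36) and Fads1 (-0.94) among them, and 2 rose, Gpam (1.33) and Dgat1 (0.69), with 6 lower and 2 higher adjusted over the list alone (camera lower, adjusted p = 0.0215, and adjusted p = 0.428 with an estimated correlation). The lipogenesis list was not called without the filter (mean -0.05 against -0.29) or with the stricter filter (-0.24).

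Glucocorticoid-responsive genes rose in 10 of 16 members in liver, 14 adjusted over the list alone, with Tat, Cdkn1a (2.38), Per1 (2.08) and Sgk1 (1.85) (camera, adjusted p = 4.55e-10, and adjusted p = 0.428 with an estimated correlation). Immediate early genes rose in 9 of 22, 14 adjusted over the list alone, with Gadd45b (2.13 at the list's probe set), Zfp36 (1.96) and Fos (1.92) (camera, adjusted p = 1.46e-05, and adjusted p = 0.639 with an estimated correlation). Erythroid genes rose in 3 of 27, also 3 adjusted over the list alone, Ermap (0.80), Slc25a37 (0.65) and Alas2 (0.51) (camera, adjusted p = 0.00052, and adjusted p = 0.428 with an estimated correlation). Mitochondrial lists were lower: 7 of 76 oxidative phosphorylation genes fell (10 lower and 1 higher adjusted over the list alone), with Ndufa13 (-0.93) and Ndufv3 (-0.90), and 7 of 60 mitochondrial ribosome genes (7 adjusted over the list alone), with Mrpl49 (-1.01). Of 39 fatty acid oxidation genes 6 fell and 2 rose (12 lower and 3 higher adjusted over the list alone), with the ketone body dehydrogenase Bdh1 (-1.76), Eci1 (-1.12) and Acaa2 (-1.04) lower and Pdk4 (2.29) higher. Camera gave adjusted p = 1.84e-06, 0.000617 and 0.00389 for these 3 lists, and adjusted p = 0.743, 0.428 and 0.743 with an estimated correlation. The tricarboxylic acid cycle list had 1 rise, Fh1 (1.13), and 1 fall, Mpc1 (-1.03), of 24, with 2 each way adjusted over the list alone (limma camera, adjusted p = 0.276).

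In liver 941 of 13577 tested probe sets passed (limma, adjusted p under 0.05), 471 higher and 470 lower, standing for 355 and 367 genes, with 44 higher and 42 lower by 4-fold or more. Leaving out wild-type replicates 1, 2 and 3 in turn gave 328, 252 and 196, and leaving out null replicates 1, 2 and 3 gave 266, 1796 and 246. Of the 24 named genes 14 passed without each array in turn. Plk3, Cry2, Inhba and Cyp4a12a passed where they were tested but fell under the filter without some arrays, and Ddit4, Aox3, G0s2, Akr1c14, Pcolce2 and Pbld2 lost the call. Without null replicate 3 these 6 stood at 3.16, -3.13, -2.47, -2.63, -2.36 and -2.72 and none passed.

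In salivary tissue the cell cycle and cholesterol synthesis lists were lower by camera. The brown fat transcript Ucp1 was high in all null arrays and, among wild-type arrays, in replicate 3 alone, as given below. The ribonucleotide reductase subunit Rrm2 fell by 2.71 ± 0.17 (SE), from 10.01 ± 0.15 to 7.30 ± 0.29 (SD, n = 3; limma, adjusted p = 0.000168). Of 36 measured cell cycle genes 27 fell and 9 did not pass (29 adjusted over the list alone), among them Mcm6 (-2.22), Tk1 (-2.07) and Bub1b (-1.95), and all 36 estimates lay below 0 (camera, adjusted p = 2.57e-25, and adjusted p = 0.215 with an estimated correlation). The DNA polymerase Pole (-2.56), the epigenetic regulator Uhrf1 (-2.29), the repair helicase Rad54l (-2.12), the flap endonuclease Fen1 (-2.06) and Hells (-2.01) were also among the named falls. The isomerase Idi1 fell by 2.62 ± 0.17 (limma, adjusted p = 0.000168), and 8 of 18 cholesterol synthesis genes fell with 10 not passing (11 lower and 1 higher adjusted over the list alone), including Msmo1 (-2.44), Cyp51 (-1.77) and Sqle (-1.57) (camera, adjusted p = 2.04e-08, and adjusted p = 0.307 with an estimated correlation). Klk1, the kallikrein of salivary ducts, fell by 3.43 ± 0.31 (limma, adjusted p = 0.00066), with both other probe sets in the same direction, and Spink4 (-2.50) and Psat1 (-2.17), of serine synthesis, fell too.

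Rises in salivary tissue were named for genes of several kinds. The desaturase Scd1 rose by 3.94 ± 0.29 (limma, adjusted p = 0.000308), with Gadd45g (4.0), Pdk4 (3.94), the peroxidase Gpx3 (3.68), Trp53inp1 (3.60), the acyl-CoA synthetase Slc27a2 (3.54), titin Ttn (2.94), Rgs2 (2.94), histidine decarboxylase Hdc (2.79), the peroxisomal enzyme Ehhadh (2.77), Cebpd (2.67) and Bpifb2 (2.59). Wild-type means of Gadd45g, Slc27a2, Ttn, Hdc and Bpifb2, and null means of Pole, Spink4, Rad54l, Fen1 and Hells among the falls, lay under the level of the filter, so background bounds these changes. Fatty acid oxidation genes rose in 4 of 40 members, Echs1 (1.16) besides Pdk4, Slc27a2 and Ehhadh, with 4 adjusted over the list alone (camera, adjusted p = 0.00019, and adjusted p = 0.741 with an estimated correlation). The adipose list had 0 of 15 passing and 10 higher adjusted over the list alone, with Pparg at 4.24 (limma, adjusted p = 0.0627) and Adig at 1.22 (camera higher, adjusted p = 0.000108, and adjusted p = 0.655 with an estimated correlation). Fasting genes rose in 3 of 16, Pdk4, Lpin1 (2.57) and Irs2 (1.77), with 5 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.025, and adjusted p = 0.526 with an estimated correlation). Beside these lists the brown fat transcript Ucp1 read 5.99, 4.04 and 12.14 in wild-type and 11.31, 12.75 and 11.02 in null replicates 1, 2 and 3. With Ucp1 as a covariate, an alternative chosen after the data were seen, the list means were 0.07 against 0.70 for fatty acid oxidation, 0.24 against 1.76 for adipose and 0.44 against 0.79 for fasting genes, and camera called none of the 3. Camera did not call the fatty acid oxidation list without null replicate 2 (mean 0.41), nor the fasting list without null replicate 2 (0.71) or wild-type replicate 1 (0.70), with array weights (0.76) or without the mean-variance trend (0.79). In the tricarboxylic acid cycle list 0 of 24 passed, as adjusted over the list alone, with Pcx at 0.88 (limma camera, adjusted p = 0.0712), and in the oxidative phosphorylation list 2 of 79 rose and 3 fell, Atp5g1 (-1.40) among them, with 2 higher and 3 lower adjusted over the list alone (limma camera, adjusted p = 0.438). The means of both turned with Ucp1 as a covariate, from 0.34 to -0.15 and from 0.14 to -0.17, and camera called the second lower (adjusted p = 0.00856). Without wild-type replicate 3, null replicate 1 or null replicate 3 the first was called higher (means 0.58, 0.45 and 0.48), as it was after quantile normalization (0.35), and the second was called without wild-type replicate 3 (0.28) or null replicate 1 (0.26) and, uncalled, ranked lower by camera without wild-type replicate 1 (0.08) or null replicate 2 (-0.07).

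Glucocorticoid-responsive genes rose in 8 of 15 members in salivary tissue, 13 adjusted over the list alone, with Tsc22d3 (2.49), Cdkn1a (2.32), Sgk1 (1.90) and Klf9 (1.87) (camera, adjusted p = 9.81e-11, and adjusted p = 0.385 with an estimated correlation). Against wild-type replicate 3, the 1 wild-type array of high Ucp1, the list mean was 1.19, and against wild-type replicates 1 and 2 it was 1.56. Immediate early genes rose in 5 of 22, 10 adjusted over the list alone, with Fos (1.43) and Egr1 (1.07), and circadian genes in 5 of 12, 7 adjusted over the list alone, with Per1 (1.49) and Usp2 (1.02). Camera gave adjusted p = 0.000149 and 0.00019 for them, and adjusted p = 0.618 and 0.385 with an estimated correlation. Heat shock genes fell in 3 of 16, Hsph1 (-0.89), Hsp90aa1 (-0.65) and Hspd1 (-0.55), with 6 lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.0199, and adjusted p = 0.385 with an estimated correlation). That list was not called without null replicate 2 (mean -0.22 against -0.25).

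In salivary tissue 1116 of 13576 tested probe sets passed (limma, adjusted p under 0.05), 475 higher and 641 lower, standing for 382 and 449 genes, with 43 higher and 23 lower by 4-fold or more. With Ucp1 as a covariate 276 passed, and without the 2 wild-type arrays with low Ucp1 29. Of the gene results named for salivary tissue 20 of 60 lost the call in the first and 35 of 57 in the second, and Sdhb (0.52) changed direction in both (-0.04 and -0.02). Leaving out wild-type replicate 1 or 2 or null replicate 1 or 3 gave 536, 321, 520 and 549, and 15 of the 24 named genes passed without each array in turn. Ttn and Hdc passed where they were tested but fell under the filter without some arrays. Without wild-type replicate 1, Gadd45g (3.59), Gpx3 (3.72), Slc27a2 (3.55) and Bpifb2 (2.50) did not pass, and without wild-type replicate 2, Slc27a2 (2.54), Ehhadh (2.48), Pole (-2.57) and Rad54l (-2.05) did not.

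In brain 0 of 13577 probe sets passed over all genes (limma, Benjamini-Hochberg adjusted p under 0.05), while 1426 had an unadjusted p under 0.05 and 679 were expected by chance. The genes with the smallest p did not pass: Ptov1 differed by 1.75 ± 0.22 (SE; limma, adjusted p = 0.0991), the protease inhibitor Timp3 by 1.11, Faap24 by 0.92, Msl1 by 0.83 and Lpcat1 by 0.79, and on the other side Prss40 by -1.04, the phosphatase subunit Ppp1cb by -0.93, the 14-3-3 protein Ywhaq by -0.86, Rpe by -0.66 and the mitochondrial protein Chchd10 by -0.59. Of their other probe sets, 1 of 2 for Timp3 and 2 of 2 for Msl1 went the opposite way. Without null replicate 2 the count was 56.

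Lists of genes still lay apart in brain by camera. All 14 glucocorticoid-responsive genes had estimates above 0, with Per1 at 1.0, Klf9 at 0.74, Tsc22d3 at 0.65 and Mt2 at 0.57. Of these 14, 0 passed over all genes and 9 were higher adjusted over the list alone (camera, adjusted p = 8.59e-09, and adjusted p = 0.7 with an estimated correlation). Cell cycle genes were lower, with 23 of 27 estimates below 0, 0 passing and 1 lower adjusted over the list alone, such as Mcm6 at -0.85 and Rrm2 at -0.54 (camera, adjusted p = 7.19e-05, and adjusted p = 0.7 with an estimated correlation). Smooth muscle and fibroblast genes (Col1a2 at 0.79, Postn at 0.56), immediate early genes (Ccn2 at 0.98, Klf2 at 0.65) and ribosomal protein genes (Rpl41 at 0.36) were higher, with 0 of 17, 0 of 20 and 0 of 41 passing and 0 adjusted over each list alone. Camera gave adjusted p = 0.00135, 0.0327 and 0.000621 for these 3, and adjusted p = 0.7, 0.75 and 0.7 with an estimated correlation. Without null replicate 1 the first was not called (mean 0.10 against 0.33) nor the immediate early list (0.04 against 0.29), and the latter was not called without wild-type replicate 2 (0.25), with the stricter filter (0.31) or without the mean-variance trend (0.29) either. The ribosomal list was not called after quantile normalization (mean 0.06 against 0.11). Fatty acid oxidation, tricarboxylic acid cycle and oxidative phosphorylation genes had 0 of 32, 0 of 23 and 0 of 77 passing and 0 adjusted over each list alone, with Acadvl at 0.49, Mdh1 at -0.44 and Cycs at -0.52, and limma camera called none of them (adjusted p = 0.89, 0.264 and 0.297). The mean of the last turned from -0.03 to 0.01 without null replicate 1, and camera's ranking of the first (mean 0.05) turned without wild-type replicate 3 (0.02) or with the stricter filter (0.02).

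**Figure D2:**
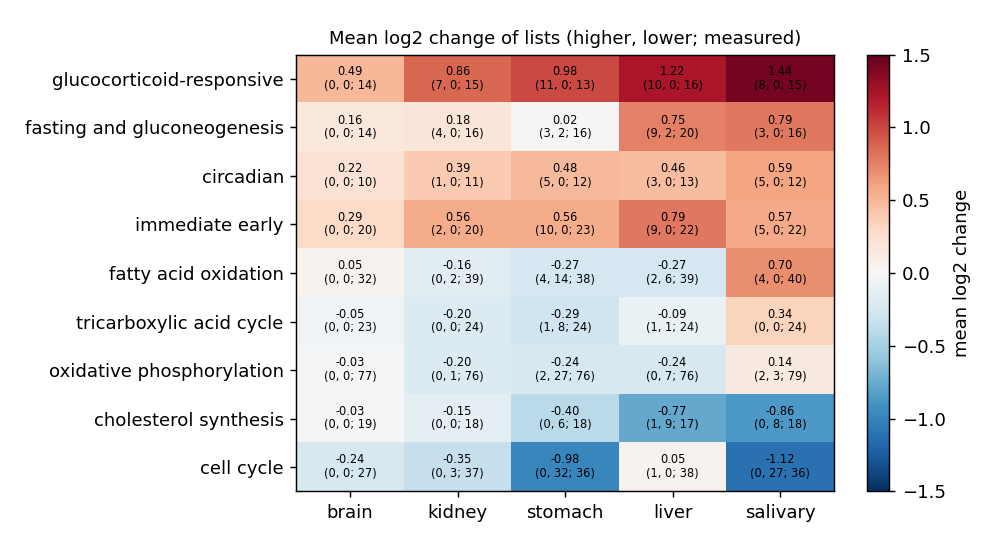
Mean log2 change (colour and number) of 9 gene lists in each tissue, null minus wild-type, with the numbers of members that passed as higher and lower and the number measured in brackets. The glucocorticoid-responsive list ran from 0.49 in brain to 1.44 in salivary tissue, and the cell cycle list from -1.12 in salivary tissue to 0.05 in liver.

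Over all tissues together, the average effect asked which genes moved on average over the organs. Klf9, a glucocorticoid-induced transcription factor, rose by 1.33 ± 0.09 on average (SE; limma, adjusted p = 8.76e-10), Cebpd by 2.17 ± 0.19 (limma, adjusted p = 2.53e-08), Pim3 by 1.52, Rgs2 by 1.21, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, by 1.03, Crebrf by 0.86, Serinc1 by 0.61 and Wdr45 by 0.60. Estimates for all of these but Rgs2, at -0.01 in brain, were above 0 in all 5 tissues. Dhrs1 fell by 1.24 ± 0.12 (limma, adjusted p = 8.22e-08), Rrm2 by 0.95, squalene epoxidase Sqle by 0.79, the cell cycle genes Skp2, Cdk1 and Cks2 by 0.74, 0.68 and 0.59, Ddx39a by 0.59, and Atp4a by 1.12, which rests on stomach. Of 16690 tested probe sets 3753 passed, 1898 higher and 1855 lower, of which 1002 and 797 had the same sign in all 5 tissues. With array medians made equal the split was 1372 higher and 2150 lower. Xist was low in wild-type replicate 3 and null replicate 1 in all 5 tissues, so arrays with the same number in different tissues may come from 1 animal. The average fit treats all arrays as separate, so its p-values and counts may overstate the evidence. With the numbers taken as animals in a random block 3261 passed. That fit uses 1 correlation for all probe sets (0.03) and does not reduce the comparison to 3 against 3 animals.

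Many calls recurred between tissues. In 3 or more tissues 99 probe sets of 78 genes passed in the same direction, 68 higher and 31 lower, and 12 passed in 4. Cebpd, Klf9, Errfi1, Tsc22d3, Sgk1, Nfkbia, Pim3 and Crebrf rose, and Atp5g1, a subunit of ATP synthase, and Dhrs1 fell, in kidney, stomach, liver and salivary tissue. Pdk4, Ddit4, Txnip, Sesn1, Per1, Fos and Trp53inp1 rose in stomach, liver and salivary tissue, where the cholesterol synthesis genes Hmgcs1, Msmo1, Cyp51 and Sqle and the chaperones Calr and Hspa5 of the endoplasmic reticulum fell. Cdk1, Cks2, Ube2c and Rbl1 fell in kidney, stomach and salivary tissue. Stomach and salivary tissue shared 152 higher and 270 lower probe sets against 49.7 and 75.3 expected of independent lists, liver and salivary tissue 116 and 50 against 14.8 and 17.8, and stomach and liver 134 and 97 against 47.2 and 46.0. Tissues of 1 animal are not independent, and part of this excess may come from that.

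**Figure D3:**
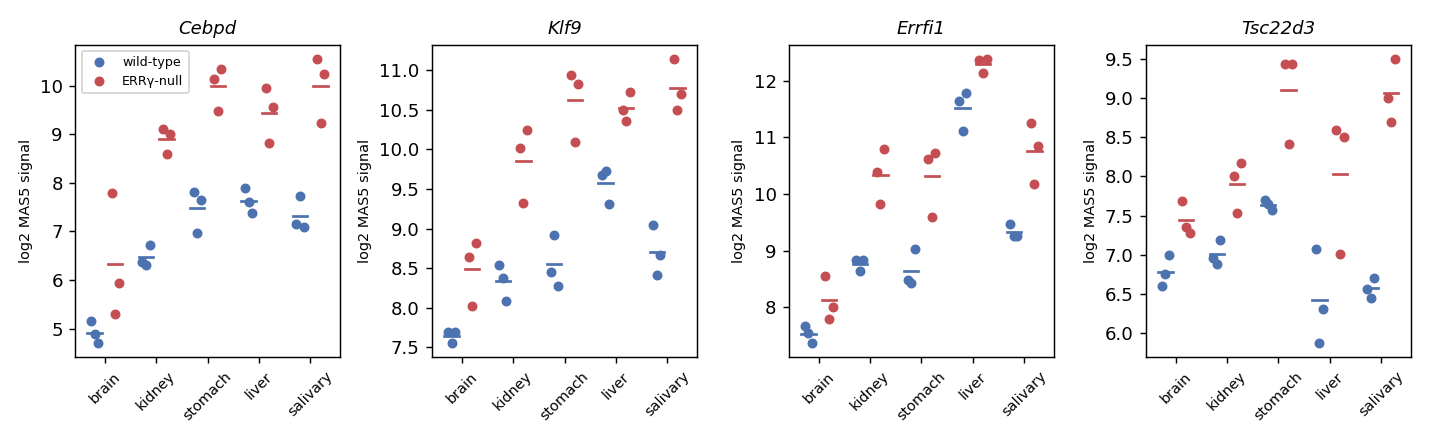
Log2 MAS5 signal of 4 genes in the 5 tissues, with 1 point per array and a line at the mean of each group of 3. Estimates for Cebpd, null minus wild-type, ran from 1.42 in brain to 2.67 in salivary tissue, and brain did not pass its own test for any of the 4.

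A test of the difference between tissues asked which effects depended on the organ. Atp4a differed (F = 143; limma, adjusted p = 6.79e-13), at -5.04 in stomach and between -0.24 and 0.00 elsewhere. Its wild-type means in the other tissues, 5.59 to 5.74, lay near its null stomach mean of 5.43. A like fall was not possible there, so this difference follows where the gene is expressed. Scd1 (F = 81.9; limma, adjusted p = 2.83e-10) fell by 1.76 in stomach and rose by 3.94 in salivary tissue. Got1 (F = 53.6; limma, adjusted p = 2.56e-08) rose by 3.43 in liver and fell by 1.12 in stomach. The flavin monooxygenase Fmo1 (F = 43.5; -1.53 in liver, 0.85 in salivary tissue), Gucd1 (F = 42.5; 1.86 in salivary tissue), Grina (F = 40.9; -1.15 in stomach, 1.21 in salivary tissue) and Csrp2 (F = 38.5; -1.11 in stomach) had limma adjusted p of 1.96e-07, 2.04e-07, 2.57e-07 and 4.27e-07. Ceacam1 (F = 37.1; limma, adjusted p = 5.53e-07) stood at 5.02 in stomach at a probe set that lay under the filter there. Of the 16 genes named for their average effect 15 differed between tissues by this test, such as Rgs2 (F = 22.0; limma, adjusted p = 2.54e-05), Pim3 (F = 15.8; limma, adjusted p = 0.000173) and Rrm2 (F = 36.7; limma, adjusted p = 5.56e-07), which stood at -2.71 in salivary tissue and 0.14 in liver. The other, Cebpd, did not pass (F = 1.62; limma, adjusted p = 0.383). Effects differed between tissues for 2550 of 16690 probe sets, of which 1213 were also called on average, and for 1138 without stomach. Sample differences that followed genotype within a tissue can enter these counts. The control 3' minus 5' gap was larger by 1.13 in null stomach, against -0.19 to 0.05 in the other tissues. Alb was high in 2 wild-type stomach arrays and Ucp1 low in 2 wild-type salivary arrays. The F test does not separate these from an effect of ERRγ.

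Genes near Esrrg were compared with all others, because null mice on a mixed background can carry a segment of the targeted strain around the locus. Within 20 Mb of Esrrg in the mouse gene table used (GRCm38.p6), 27 of 120 tested genes passed in stomach (Esrrg itself counted among both), 11 of 123 in liver, 9 of 116 in salivary tissue, 0 of 115 in kidney and 0 of 116 in brain. These shares, 22.5%, 8.94%, 7.76%, 0% and 0%, stood against 22.1%, 7.04%, 8.13%, 0.867% and 0% of other genes. Fisher's exact test, two-sided, gave adjusted p = 1 in each tissue and on average. In brain, where 0 genes passed, it could give no other result, and in kidney few genes passed anywhere. The test compares shares and does not weigh single neighbours. Pacc1 rose in stomach (0.78), liver (0.90) and salivary tissue (1.10), though calls also recurred between tissues in genes elsewhere. A carried segment that changes a few genes is therefore left open.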

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

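Of the tests in this part, those of equally bright probe sets, of the spread of Alb and of other splits, and the settings with the Gapdh gap or Alb, were chosen after the result was seen. The test of the gap in the other tissues was written before its result.

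A difference between tissues was found by its own F test for 2550 probe sets. Sample differences that followed genotype within a tissue, as the control gap did in stomach, can enter this count. Atp4a, near background in wild-type arrays of the other tissues, could fall only in stomach. The 8 named genes were Atp4a (F = 143), Scd1 (F = 81.9), Got1 (F = 53.6), Fmo1 (F = 43.5), Gucd1 (F = 42.5), Grina (F = 40.9), Csrp2 (F = 38.5) and Ceacam1 (F = 37.1). Only 1 of the 10 splits of the 6 replicate labels, the real one, gave as many, and the highest other gave 5. Every other split mixes the genotypes, which by itself lowers such counts. With 10 splits a share under 0.05 cannot be reached.

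The control transcripts, which no comparison used, showed a signal as well: the Gapdh 3' minus 5' gap was larger by 1.18 in null than in wild-type stomach, and the mean gap of Gapdh and Actb was larger by 1.13 there, against values between -0.19 and 0.05 in the other tissues. The first pattern weighed is the breadth of change in stomach, 3186 probe sets with this larger gap. If RNA integrity were its cause, probe sets that follow the gap among the 24 arrays of other tissues should change in stomach. Their correlation was 0.0808 (p = 0.29 over 99 permutations, whose highest value was 0.257), which leaves RNA integrity open. With the Gapdh gap as a covariate 2 probe sets passed. Of 74 named gene results of stomach 70 lost their call with their direction kept, 3 stayed as they were and 1 changed direction. A covariate that differs with genotype widens the errors by construction. Only 1 of the 10 splits of the 6 stomach arrays, the real one with 3186, gave as many calls, and the highest other gave 0. Every other split mixes the genotypes, so any difference that follows genotype, the gap included, keeps its count low. The splits therefore cannot separate RNA integrity from genotype.

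The fall of Atp4a and Atp4b within that breadth is the next part of this pattern. Of 504 other probe sets at least as bright in wild-type stomach, 0.198% fell by 4 or more on the log2 scale, namely 1, for Csn1s2a, which argues against RNA integrity as the cause of this fall. Neighbouring tissue in the wild-type samples was expected to vary as Alb did. The larger SD of Atp4a and Atp4b was 0.046 of that of Alb. In wild-type liver Atp4a read 5.59 ± 0.24 and Atp4b 5.98 ± 0.20 (SD, n = 3), so liver could not supply these transcripts. The ratio was thus small whatever the share of liver, and it does not test whether the groups held different parts of the stomach. With the Gapdh gap as a covariate the differences were -4.96 and -4.72, and without the 2 wild-type arrays of high Alb -5.14 and -4.65. A loss of parietal cells and a lower expression within them may both lie behind this fall, and tissue RNA cannot separate them.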

How the results depend on the processing

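Covariates for the Gapdh gap, Alb and Ucp1, and fits without arrays of high Alb or low Ucp1, were chosen after seeing the data, and the other settings before. Planned settings held 339 named gene results, of which 223 were called and the rest had no call to lose. Of the 339, 332 kept direction and side of the threshold with array weights, 337 with a floor and 335 with a larger pseudocount. With equal medians 322 did, with Xist as a covariate 321 and with the replicate block 308. No filter ended 59 calls, no mean-variance trend 53 and the fit over 30 arrays 41. Leaving out arrays ended calls for 105 genes, as fewer samples can. Of 55 list results called by camera, 36 kept the call in every leave-one-out fit and planned setting apart from the test itself. With an estimated correlation 0 of all 67 list results passed, and with fry 29 did, whether or not camera had called them.

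Counts of probe sets that passed moved as follows, and the cause was not tested. In brain (0) adjusted p under 0.10 gave 2, quantile normalization 2, the fit over 30 arrays 5 and array weights 5. In kidney (106) adjusted p under 0.10 gave 305, no filter 26, equal medians 160, the fit over 30 arrays 37 and no mean-variance trend 20. In stomach (3186) a 1.5-fold minimum gave 2042, the Gapdh gap as a covariate 2, Alb as a covariate 504 and leaving out the 2 wild-type arrays of high Alb 28. In liver (941) adjusted p under 0.10 gave 1588, no filter 527, the fit over 30 arrays 1988, no mean-variance trend 534 and array weights 1533. In salivary tissue (1116) adjusted p under 0.10 gave 1852, the fit over 30 arrays 2198, the replicate block 515, Ucp1 as a covariate 276 and leaving out the 2 wild-type arrays of low Ucp1 29. The average effect (3753) gave 591 with a 1.5-fold minimum, and the difference between tissues (2550) gave 1138 without stomach. Leave-one-out fits ranged from 0 to 56 in brain, 4 to 295 in kidney, 1461 to 3601 in stomach, 196 to 1796 in liver and 321 to 1378 in salivary tissue. Where 1 wild-type array was left, it was assumed to vary like the null arrays.

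Some values changed direction, and the cause was not tested. By camera's ranking the brain fatty acid oxidation list (mean 0.05) turned with the stricter filter (0.0231) and without wild-type replicate 3, and its leave-one-out means ran from 0.0209 to 0.0760. The brain oxidative phosphorylation list (-0.03) ran from -0.0437 to 0.00695. The stomach hepatocyte list (-1.48) came to -0.29 with the Gapdh gap, 0.00393 with Alb and -0.14 without high Alb, and Apoa1 (-2.12) to 0.30 with the gap. Esrrg in liver (-0.02) was 0.0195 with array weights and -0.17 to 0.12 in leave-one-out fits, and in salivary tissue (-0.03) 0.0169 with Ucp1, 0.0467 without low Ucp1 and -0.16 to 0.0567. In salivary tissue Sdhb (0.52) was -0.0386 with Ucp1 and -0.0233 without low Ucp1, the tricarboxylic acid cycle list (0.34) -0.15 and -0.15, and the oxidative phosphorylation list (0.14) -0.17 and -0.14, with a leave-one-out range from -0.0665 to 0.28 and a turn by camera's ranking without wild-type replicate 1 (0.0790) or null replicate 2. Esrrg has 1 probe set, so testing each could give no other value.

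Replicate numbers do not pair wild-type with null arrays: within tissues, same-numbered arrays of both genotypes had a mean correlation of -0.04, with 1 of 15 over 0.1. Across tissues same-numbered arrays of a genotype had means of 0.08 and 0.11, against -0.04 and -0.05 for others. With the number as a block brain gave 0, kidney 106, stomach 2474, liver 843, the average 3836 and the difference between tissues 2653. Signals near background limit what the dim probe set of Esrrg shows. The filter, on the mean over 6 arrays, left out Kcne2 in stomach and Klk1 in kidney, whose null values were low. Of 8 probe sets of the parietal cell list under it in stomach, 3 passed as lower and 0 as higher when tested without it.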

Other observations

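Tests of the gap in kidney and liver, of adipose genes in salivary tissue and of other splits, and the settings with Ucp1, were chosen after the result was seen, while the tests of milk transcripts and of salivary cell cycle genes were written before theirs. Genes of the next 2 paragraphs were chosen after their values were seen, unless the report names them.

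Among 6 chief cell genes the colipase Clps (-1.84), the pepsinogen Pgc (-1.06) and Cblif (-0.76) fell and Pga5 (0.27) and Ctse (0.23) rose in null stomach, with 2 higher and 4 lower adjusted over the list alone (limma camera, adjusted p = 0.159). Among 12 mucous cell genes Psca (-0.74) and Cldn18 (-0.51) fell and Tff1 (0.27), Gkn2 (0.29) and Anxa10 (0.25) rose (limma camera, adjusted p = 0.507).

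In salivary tissue secretory genes also went both ways, with Mucl2 (-1.65), Aqp5 (-0.82), the water channel of acinar cells, and Prpmp5 (-0.83) lower and Pip (2.0) and Pigr (1.38) higher of 21 (limma camera, adjusted p = 0.309). Of 27 chaperone and amino acid stress genes 8 fell there, Calr (-1.03), Hspa5 (-0.73), Asns (-0.99) and Phgdh (-1.10) among them, 3 rose and 16 did not pass (limma camera, adjusted p = 0.0645). In liver the bile acid transporters Abcb11 (-1.16) and Slc10a1 (-0.88) fell.

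Camera placed glucocorticoid-responsive genes higher in all 5 tissues, though in brain 0 of 14 passed singly, and fasting genes in liver and salivary tissue. None of these 7 calls held with an estimated correlation (adjusted p between 0.284 and 0.7). The salivary fasting list was not called with Ucp1 as a covariate (mean 0.44) or without wild-type replicate 1 or null replicate 2. Null replicate 2 had the smallest mean rise of the glucocorticoid-responsive list in each tissue, 0.63 in stomach against 1.18 and 1.15, and the highest Wap and Csn2 of the null stomachs. The labels do not say that a number marks 1 animal in all tissues. If it does, this match rests on 1 animal and is not 5 separate observations. Of 7 milk genes not seen before, 3 passed as lower in stomach. In wild-type stomach 2 of them lay above other tissues, Glycam1, which read 8.24 in wild-type and 2.28 in null stomach, and Muc15, which differed by 0.50 and did not pass. Olah (-0.13), Lalba (-0.56) and Glycam1 lay under the filter. In a longer list of 14, Xdh (0.84) passed as higher.

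Lower milk intake of null pups was tested on this pattern with those 7 genes, whose median change in stomach was -1.11, with 6 of 7 lower. This median met the bound set beforehand for lower milk intake. Wap, Csn2, Csn3 and Csn1s1, which lay above other tissues in wild-type stomach, fell as well, but they had been seen before the test. Of the 7, 5 did not lie above other tissues in wild-type stomach, a condition set after these values were seen. The median of the 7 therefore does not measure milk alone and leaves the question open. The list was shortened from the longer one before any of these values were seen, and that one, with a median of -0.0667 and 8 of 14 lower, leaves it open too. RNA integrity as the source in kidney and liver is argued against by a gap no larger in null arrays (-0.0867 in kidney, the larger of both differences). Stress, low energy intake and a direct effect of ERRγ may each contribute, and the design does not separate them.

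In salivary tissue the adipose and fatty acid oxidation lists were higher in null arrays, where Ucp1 was high in all 3 null arrays and in wild-type replicate 3 alone. Against that array the mean of the adipose list was 0.10, which is consistent with a different share of brown fat in the dissected samples. The cell cycle list lay at -1.18 against it, with 36 of 36 genes lower, and at -1.15 with Ucp1 as a covariate, a condition added after its value was seen, and both values lean on that 1 wild-type array. Brown fat that diluted other cells would lower gland transcripts by as much. Over all 6 arrays the glandular duct and secretory lists had means of -0.15 and -0.11 (SD over members 0.80 and 0.82). Their medians were -0.06 and -0.12, against a mean of -1.12 and a median of -0.99 for the cell cycle list. Members of the gland lists went both ways, with 1 of 18 and 2 of 21 at or below the cell cycle mean. These values, compared after they were seen, argue against brown fat as the whole cause of the cell cycle fall.

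Splits of the 6 arrays of a tissue into 3 and 3, 10 in number, were counted by how many gave as many calls as the real one. In kidney the real split gave 106 and the highest other 0, in liver 941 and 0 and in salivary tissue 1116 and 1, so 1 split, the real one, reached the count in each. In brain the real split gave 0, as did all 10. For the average over tissues the real split of the replicate labels gave 3753 and the highest other 1. Every other split mixes the genotypes, so low counts there do not tell what lies behind a difference between the groups. With 10 splits a share under 0.05 cannot be reached.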
